A study of Mus musculus with 18 samples.

How the data were processed

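The data are RNA sequencing of cultured satellite cells from mouse tibialis anterior muscle, in 9 control and 9 scKO libraries. Per the labels' protocols, cells grew on matrigel in growth medium, the scKO group was given 4-hydroxytamoxifen at 1 µM for 2 days, and RNA was extracted with Isogen II and purified on RNeasy columns. The deposited table holds raw counts of unique molecular identifiers (UMIs) per gene, per the name of the table, with 50689 features and 1 column per library. HISAT2 and HTSeq are named in the submitters' processing notes, with no version or setting. The same notes name the rat build Rnor_6.0, while the feature identifiers are mouse Ensembl genes; the identifiers were used as deposited. The library kit, the annotation release, the use of strand and the length of the UMIs are not stated in the labels. The highest count was 4096, which equals 4 to the power 6, the number of different UMIs of 6 bases, and counts of abundant genes in deep libraries lay near that value.

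Of the features, 50376 were paired with a gene symbol and 313 were not; the latter held 0.041% of counts. Positions and gene models came from GENCODE release M21 (GRCm38). Totals ranged from 420197 to 5986128 counts per library. A count of 3 in a library, taken as the floor, corresponded to 0.375 to 8.96 CPM, counts scaled to the library total. Standard deviations and p-values, other than those of Fisher's exact test and of camera, cover the spread between libraries. Camera compares the genes of a list with the other genes. At the preset correlation its p rests on an assumed correlation and does not measure how a list's level varies between libraries. Counting error limits genes with few counts in the 13 shallow libraries.

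Genes were filtered with filterByExpr of edgeR 4.0.16 using the group (7662 kept) and scaled by TMM. Groups were compared with the quasi-likelihood test of edgeR with robust dispersions, in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists fixed before the data were examined were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, over the 33 lists with at least 5 tested members. Camera was repeated with a correlation estimated from the data. The fry test of limma was run beside it; its directional test, which asks whether a list's genes move on balance, called 7 lists in the model of the group alone. Single values and list levels were compared by exact two-sided permutation tests, over all splits or within depth classes, and Benjamini-Hochberg adjusted over the lists. Levels per gene are CPM on TMM-scaled totals.

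The main model, chosen before the data were examined, had the group alone. After the principal components showed 5 deep and 13 shallow libraries, a model with the depth class as a covariate and models of each class alone were added, chosen after seeing the data, as were counts corrected for UMI collisions and models without 4 shallow libraries that stood apart. The covariate does not use the group, and each class holds both groups.

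Genes to name were the Hox genes that passed the filter, the tested myogenic regulators as values or as a range, and up to 4 members with the smallest p of each list described. Others were the 10 genes with the largest change in each direction past the threshold, with a mean of at least 5 CPM and no predicted-gene symbol, and the 5 genes with the smallest p in each direction. This rule was written for the model of the group alone and was then applied in the same form to the model with the depth class. Some genes that this rule selects are not reported here. Genes named for the deep libraries alone in the closing section were chosen after their values were seen.

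The methods were tested on simulated data, with counts drawn from the means and totals of these libraries. For the comparison of 9 with 9 libraries over 7510 genes, edgeR recovered 71 of 100 genes changed by a fold of 2 and 96 of 97 changed by a fold of 4, with 2 calls at unchanged genes. With the depth class as a covariate it recovered 95 of 100 and 97 of 97, with 8 calls at unchanged genes. For 2 against 3 deep libraries over 7662 genes it recovered 30 of 100 and 95 of 100, with 13 calls at unchanged genes. The simulated spread was fitted over all 18 libraries with the depth class, where the biological coefficient of variation was 0.209. In the real deep libraries it was 0.0991, over 13136 genes, so these shares do not describe the real deep comparison. In the comparison of 9 with 9, camera called a list of 43 genes set to a fold of 0.75 (adjusted p = 4.59e-13) and 0 of the other lists. With an estimated correlation that list's camera adjusted p was 0.000192. Simulated genes varied independently of each other, so this cannot show how camera behaves where genes of a list vary together.

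Alternatives fixed before the data were examined were size factors by median of ratios, no count filter and a stricter one (at least 10 counts in 9 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, 1 surrogate variable from sva 3.50.0, counts thinned to the smallest total, leaving out mitochondrial and ribosomal protein genes, and leaving out each library. Duplicated libraries were looked for by a chi-square comparison of library pairs; the lowest value per degree of freedom over 72 pairs within groups was 1.85. Figures were drawn with matplotlib 3.10.9.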

Results

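RNA from cultured satellite cells, the stem cells of skeletal muscle, was sequenced in 18 libraries. The cells came from the tibialis anterior muscle of C57BL6 mice and were proliferating in growth medium. There were 9 control libraries, in which both copies of Hoxa10 carry Cre target sites, and 9 libraries labelled scKO, which also carry a tamoxifen-inducible Cre under Pax7. Per the labels, the scKO group received 4-hydroxytamoxifen at 1 µM for 2 days. The labels give no such treatment for the controls, so genotype, Cre and 4-hydroxytamoxifen differ together between the groups. They do not say whether libraries come from separate animals or cultures, so p-values of tests between libraries measure only the spread between these samples.

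The deposited counts of unique molecular identifiers (UMIs) totalled 4346150, 5986128, 917166, 821728, 819778, 666272, 670213, 498216 and 420197 in control 1 to 9. In scKO 1 to 9 the totals were 787934, 619678, 968559, 684010, 613915, 5553647, 5842408, 685258 and 5295236. Control 1 and 2 and scKO 6, 7 and 9, with over 2000000 counts each, are called deep here, and the other 13 libraries shallow. The group means were 1682872 for control and 2338961 for scKO (exact two-sided permutation p = 0.485). The depth classes, defined from the data, separated on the 1st principal component, which held 69.6% of the variance. No gene exceeded a count of 4096 in any library, which caps the share abundant genes can take in deep libraries. Below that cap, the 10 most abundant genes took 0.684% to 0.942% of counts in deep libraries and 3.98% to 7.04% in shallow ones, and mitochondrially encoded transcripts 0.848% to 1.06% and 2.65% to 3.91%, so these shares do not compare the make-up of the RNA between the classes. Control 7, 8 and 9 and scKO 1 stood apart from the other shallow libraries on the 2nd component, which held 9.69% of the variance. All 18 libraries held transcripts of the Y-linked genes Ddx3y and Eif2s3y, and the highest Xist count was 2.

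**Figure D1:**
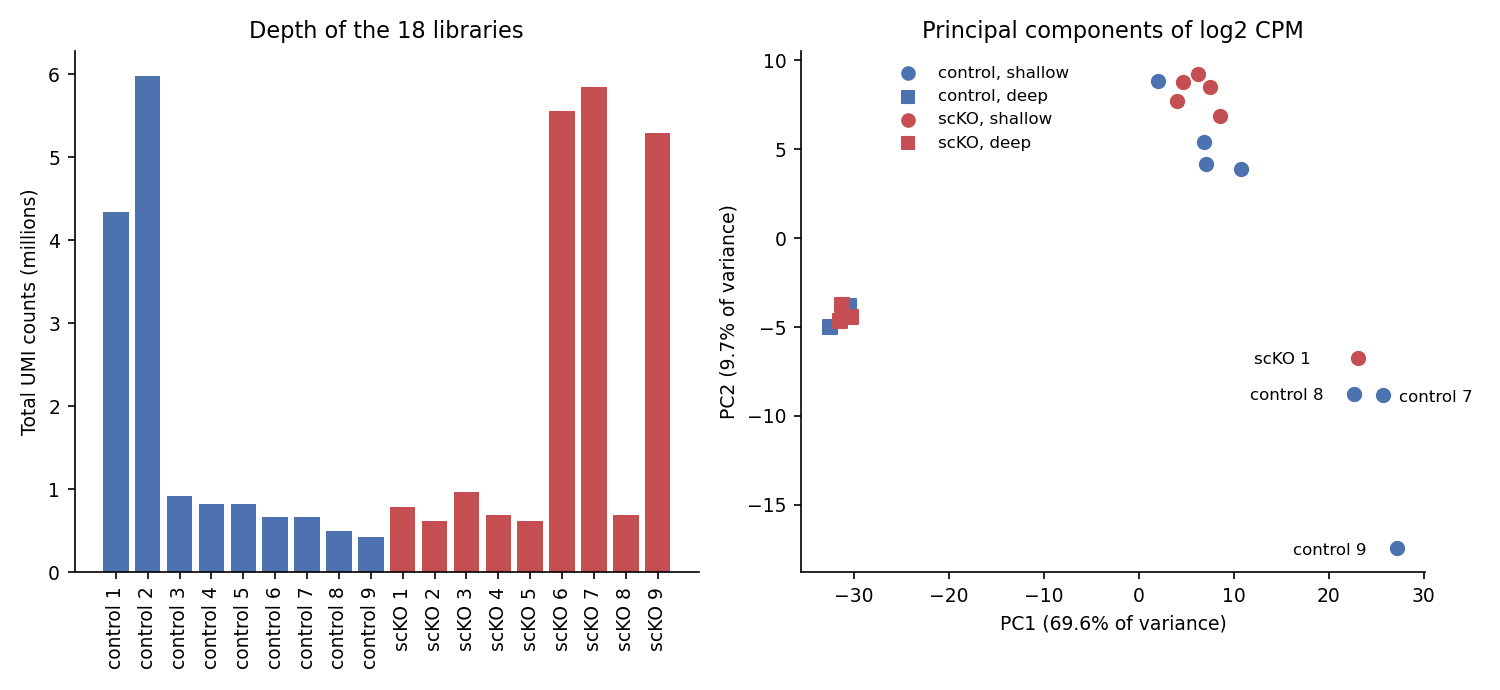
Total UMI counts per library (left, bars) and the first principal components of log2 CPM over the 500 most variable genes (right, points, with the share of variance in percent on each axis). Blue marks control and red scKO, squares mark the 5 deep and circles the 13 shallow libraries, and the 4 labelled shallow libraries lie apart from the other 9.

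Hoxa10, the homeobox gene the scKO genotype targets, was lower in every scKO library than in every control library. Its level was 36.1 ± 16.5 CPM (counts scaled to the library total; SD, n = 9) in control and 5.04 ± 2.76 CPM (SD, n = 9) in scKO, with a lowest control value of 15.3 and a highest scKO value of 10.6 CPM. The gene (ENSMUSG00000000938) lies on the minus strand of chromosome 6 at 52231197 to 52240854 in GRCm38. The log2 fold change was -2.49 (SE 0.30; edgeR adjusted p = 0.000268), and the exact two-sided permutation test of log2 CPM gave p = 4.11e-05, the smallest p these splits allow. Within the shallow libraries the log2 fold change was -3.22 (SE 0.43; edgeR adjusted p = 0.00115), and within the deep libraries -2.28 (SE 0.17; edgeR adjusted p = 3.17e-05). Shallow scKO libraries held 1 to 3 Hoxa10 counts each, 13 in all, against 133 in the shallow controls, so their remaining level is known only coarsely. The labels do not say which part of the gene lies between the Cre target sites or which part of a transcript was read.

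The neighbouring gene Hoxa9 (ENSMUSG00000038227; chromosome 6, 52223100 to 52231089) was higher in scKO once the depth class was taken into account. Its level was 7.02 ± 4.03 CPM (SD, n = 7) in shallow controls and 17.7 ± 5.18 CPM (SD, n = 6) in shallow scKO. In deep libraries it was 27.7 ± 0.479 CPM (SD, n = 2) in control and 43.1 ± 6.95 CPM (SD, n = 3) in scKO. Shallow libraries held 1 to 11 Hoxa9 counts each in control and 5 to 15 in scKO, so the shallow levels are known only coarsely. The log2 fold change was 0.84 (SE 0.19; edgeR adjusted p = 0.0434) with the depth class as a covariate, a model chosen after the data were seen, and 0.96 (SE 0.37; edgeR adjusted p = 0.641) without it. Hoxa11, on the other side of Hoxa10, had a log2 fold change of 0.07 (SE 0.19; edgeR adjusted p = 0.929) in the model with the depth class, and its reads cannot be told from those of the overlapping antisense gene Hoxa11os because the use of strand in counting is not stated. The other 6 Hox genes that passed the count filter, Hoxa7 and Hoxc6, Hoxc9, Hoxc10, Hoxc11 and Hoxc13, had log2 fold changes from -0.22 to 0.10 in that model, with no edgeR call. The 9 tested Hox genes as a list had a median of 0.08, a mean of -0.15 and a camera direction of down without the depth class (limma camera adjusted p = 0.45).

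**Figure D2:**
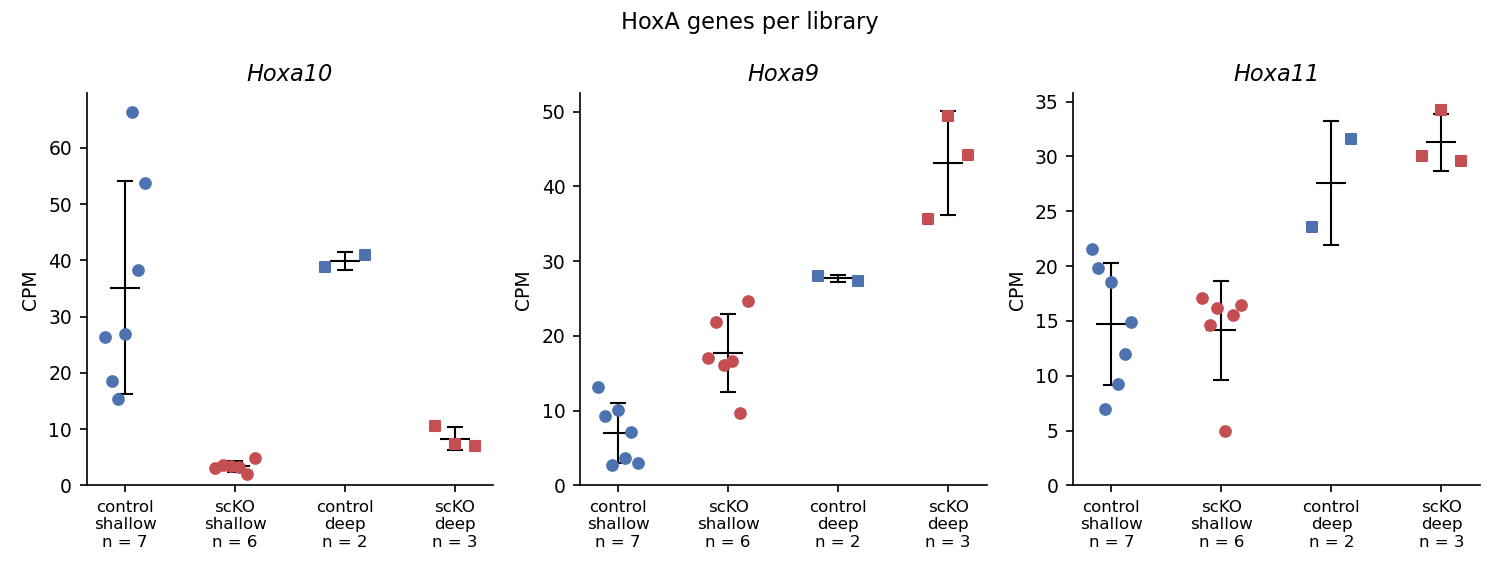
CPM of Hoxa10, Hoxa9 and Hoxa11 in each library, by group and depth class, with 7 control and 6 scKO shallow libraries (circles) and 2 control and 3 scKO deep libraries (squares). Horizontal bars mark the mean and vertical bars 1 SD; the highest Hoxa10 value in scKO, 10.6 CPM, lies below the lowest control value, 15.3 CPM.

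The comparison of scKO with control addressed what loss of Hoxa10 does to the transcripts of proliferating satellite cells. Genes of cell division were lower together in scKO. Of 45 measured genes of the G2 and M phases, 43 had negative log2 fold changes (median -0.44), and so had 42 of 43 S phase genes (median -0.43) and 50 of 54 genes of the kinetochore, spindle and spindle checkpoint (median -0.37). Genes of chromosome condensation and cohesion were lower as well, with 18 of 21 negative (median -0.27). The level of the G2 and M list lay -0.36 ± 0.19 log2 units (SD, n = 6) from the control mean in shallow scKO libraries and -0.59 ± 0.06 (SD, n = 3) in deep ones.

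These 4 lists, fixed before the data were examined, passed limma camera, with adjusted p = 2.26e-19 for G2 and M, 1.23e-13 for S phase, 4.93e-18 for kinetochore and spindle, and 1.74e-05 for condensation. With an estimated correlation between genes, their camera adjusted p was 0.00349, 0.00461, 0.00461 and 0.0029 in the same order. No single member passed edgeR over all genes tested in this model, while adjusted over the list alone 16, 2, 14 and 2 members of these lists fell. In an exact two-sided permutation test that relabelled libraries within depth classes, the S phase list differed by -0.39 log2 units with p = 5.83e-05, the smallest p these relabellings allow, and Benjamini-Hochberg adjusted p = 0.00192 over 33 lists. All 9 scKO libraries lay below the control mean of their depth class on each of the 4 lists, and on the S phase list all 9 lay below every control of their class. Inside single depth classes, camera with an estimated correlation no longer called any of the 4 (adjusted p = 0.0513 to 0.139 in shallow and 0.18 to 0.654 in deep libraries), while the preset correlation did.

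Genes of ribosome biogenesis, many of them targets of the growth regulator Myc, were lower too, with 28 of 31 negative (median -0.27; limma camera adjusted p = 5.12e-05, and adjusted p = 0.00906 with an estimated correlation). Among them Npm1 and Ncl, abundant nucleolar proteins, and Nop56, which acts in ribosomal RNA modification, had log2 fold changes of -0.38, -0.41 and -0.41, none an edgeR call; Npm1 has processed copies in the genome, so its count is less certain. DNA repair and damage genes had 20 of 26 negative values (median -0.21; limma camera adjusted p = 0.0104, and adjusted p = 0.0443 with an estimated correlation). The DNA repair call was lost without control 2 (limma camera adjusted p = 0.0589), within the shallow libraries (median -0.17, adjusted p = 0.161) and with counts thinned to the smallest total, where the median was 0.033 and the mean -0.027 over 13 members (adjusted p = 0.84). Targets of the tumour suppressor p53 were higher, with 20 of 28 positive (median 0.06; limma camera adjusted p = 0.0104, and adjusted p = 0.0182 with an estimated correlation). Of them 2 rose adjusted over the list alone. Eda2r had a log2 fold change of 0.46 and Trp53inp1 one of 0.50, neither an edgeR call over all genes. In the deep libraries the p53 list had 17 positive and 28 negative values, a median of -0.11, a mean of 0.027 and a camera direction of down (adjusted p = 0.77). The call over all libraries was lost without control 3, 5 or 6 or without scKO 3 or 4 (limma camera adjusted p = 0.0603 to 0.0778). Genes of cholesterol synthesis had a median of -0.26 over 19 members (limma camera adjusted p = 0.0348), and adjusted p = 0.108 with an estimated correlation; with the preset correlation the call was lost without control 1, 2, 3, 5 or 6 or without scKO 1, 7 or 9 (adjusted p = 0.0575 to 0.131). By the exact test within depth classes, ribosome biogenesis, DNA repair and p53 lists differed by -0.23, -0.20 and 0.12 log2 units (Benjamini-Hochberg adjusted exact p = 0.00962, 0.0131 and 0.0184), seen in 8, 9 and 9 of 9 scKO libraries. These levels use the members that passed the filter over all libraries, 28 for p53. On those 28, deep scKO libraries lay only 0.038 log2 units above deep controls (exact permutation p = 0.2). The deep median of -0.11 above rests on the members tested in deep libraries alone.

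**Figure D3:**
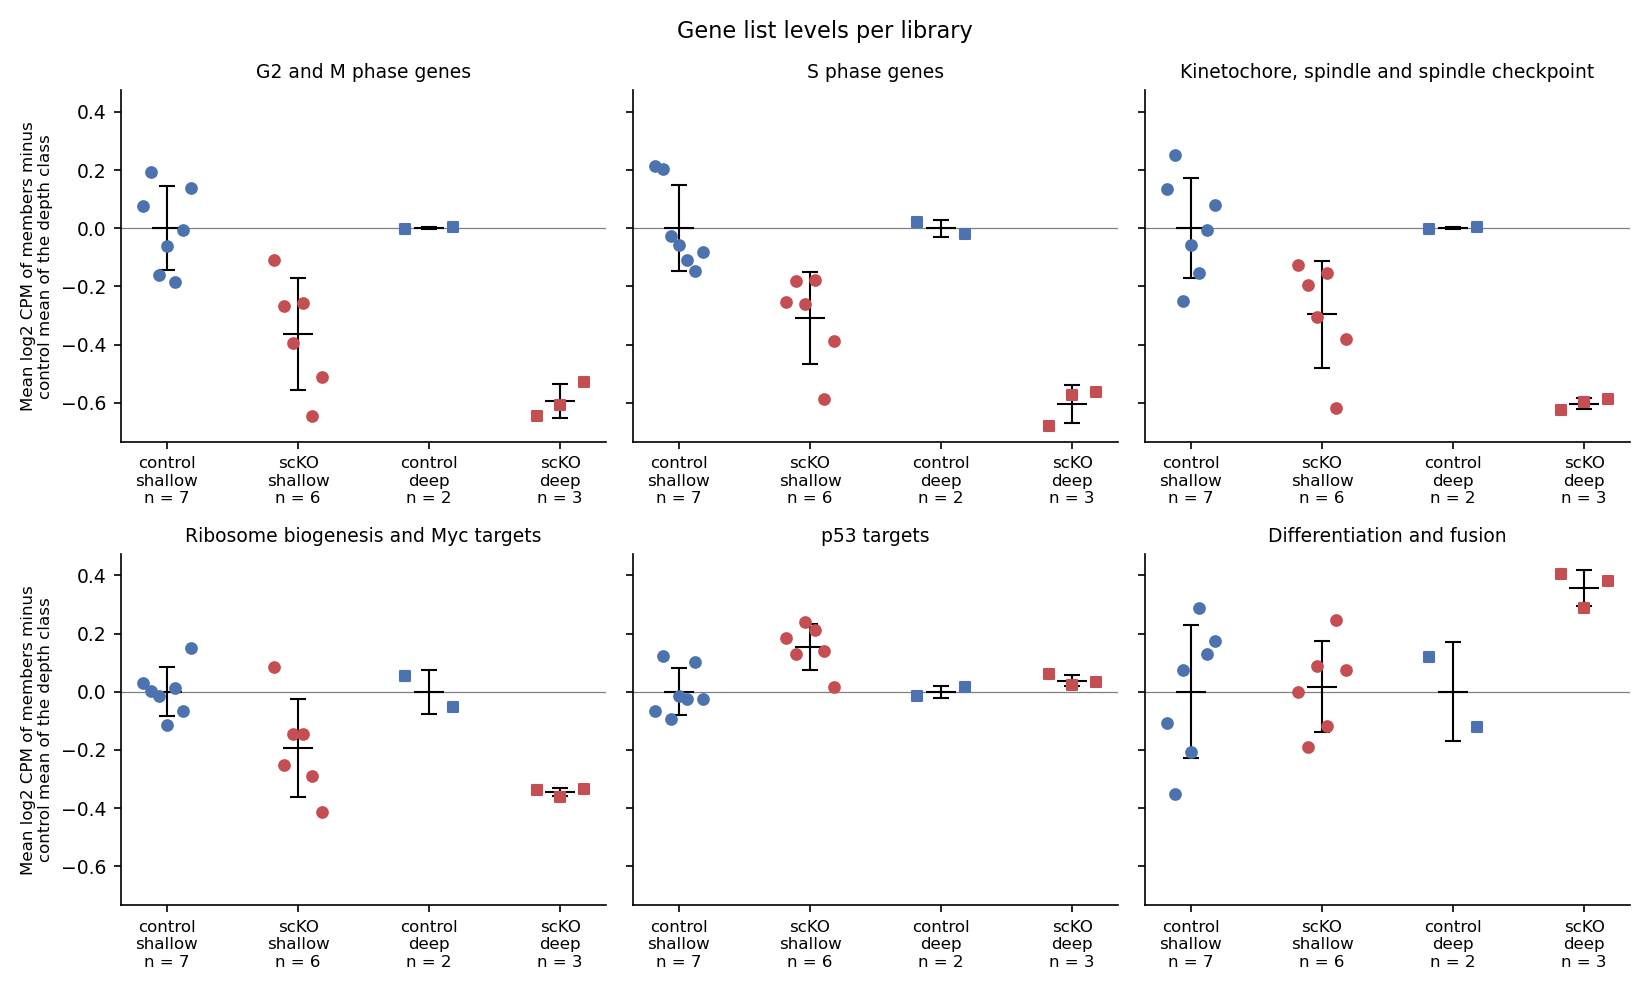
Level of 6 gene lists in each library, as the mean log2 CPM of the members minus the control mean of the same depth class, for shallow (circles) and deep (squares) libraries of control (blue) and scKO (red). Horizontal bars mark the mean and vertical bars 1 SD; all 9 scKO libraries lie below 0 on the G2 and M, S phase and kinetochore lists and above 0 on the p53 list.

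No list that describes the identity of these cells passed camera in the model of the group alone. In models given further below, the differentiation and fusion list passed at the preset correlation but not with an estimated one. Myogenic regulators (21 measured, median 0.05; limma camera adjusted p = 0.369) held Pax7, the satellite cell transcription factor, at a log2 fold change of 0.11, Myod1 at 0.05 and Myog, which drives differentiation, at 0.03, none an edgeR call. Counts of Myod1 and Myog in the deep libraries, 3192 to 4027, lay near the ceiling of 4096, so those libraries cannot show whether either changed, and the values over all 18 libraries are affected too. Within the shallow libraries Myod1 had a log2 fold change of 0.20 (SE 0.19) and Myog 0.12 (SE 0.16), neither an edgeR call. Pax7, with far lower counts, had 0.28 (SE 0.22) in shallow and -0.28 (SE 0.16) in deep libraries, neither an edgeR call. Mef2c and Mef2d, which act with the MyoD family, had log2 fold changes of 0.22 and 0.28, neither an edgeR call. Satellite cell quiescence genes had 17 of 22 positive values (limma camera adjusted p = 0.114), and limb position factors 7 of 12 (adjusted p = 0.855). The list of differentiation and fusion genes had a negative median, -0.12, and mean, -0.02, but a camera direction of up (adjusted p = 0.706). Ageing and stem cell exhaustion regulators had 11 of 16 negative values (limma camera adjusted p = 0.286), and nuclear oxidative phosphorylation genes 47 of 68 positive (adjusted p = 0.0989). Across the 25 lists that camera did not call, the TGF-beta, Wnt, growth factor, cyclin and Hox lists likewise had a median, mean and test that differed in sign. Summed markers of fibro-adipogenic, endothelial, leukocyte, smooth muscle, Schwann, tendon and fat cells gave no difference past the threshold, with the lowest exact permutation p for Schwann cell markers (745.9 CPM in scKO against 948.2 in control, exact p = 0.0981 and 0.392 after Benjamini-Hochberg adjustment). The sex-linked list gave exact permutation p = 0.0405, or 0.324 after that adjustment.

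Gene by gene, edgeR called only Hoxa10 among 7662 genes when depth was left out of the model, with 0 genes higher. At an unadjusted p under 0.05 it found 465 genes, 223 higher and 242 lower, against 383.1 that chance would give. DESeq2 called 32 genes (19 higher and 13 lower) and limma-voom 2 (1 and 1). The edgeR count was 4 without control 2, 7 without scKO 1 and 2 without scKO 3. Without the 4 libraries that stood apart it was 3.

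With the depth class as a covariate, edgeR called 52 genes in scKO, 25 higher and 27 lower. Tslp, a cytokine, rose most, from 5.43 ± 4.07 to 17.8 ± 8.42 CPM in shallow libraries (SD, n = 7 and 6; log2 fold change 1.81, SE 0.26, edgeR adjusted p = 0.00111). Shallow controls held 1 to 9 Tslp counts each, some under the floor of 3, so their level is known only coarsely. Deep libraries held 63 and 63 Tslp counts in control and 254, 320 and 221 in scKO. Gal, the precursor of the neuropeptide galanin, rose with a log2 fold change of 1.51 and Igfbp5, which binds insulin-like growth factors, with 0.89 (edgeR adjusted p = 0.00465 and 0.00112). Myh4, the fastest myosin heavy chain of mouse muscle, rose with a log2 fold change of 1.34 (SE 0.20; edgeR adjusted p = 0.00112), though its count is less certain because other myosin heavy chain genes resemble it closely, and Myom2, a protein of the sarcomere's M-band, with 0.78 (SE 0.18; edgeR adjusted p = 0.0434). Those were the 2 called members of the differentiation and fusion list, whose own camera adjusted p was 0.0408 here but adjusted p = 0.607 with an estimated correlation. Cmya5, another sarcomere-associated protein, rose with 0.91, Ccndbp1, a cyclin D-binding protein, with 0.86, and Cpeb2, which regulates mRNA translation, with 0.80. Nptx1, Hectd2os, Tcp11l2, Rab40b, Gpr146 and Nipal3 rose with log2 fold changes from 0.90 to 1.09, and the limb transcription factor Tbx15 with 0.64.

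Most of the lower genes act in cell division or DNA repair. Fisher's exact test below treats genes as independent, though genes of a list can vary together, so its p does not measure the spread between libraries. Its lists are also among those that camera called lower in the same libraries, so its p is no separate support for their being lower. Of the 27, 17 belonged to the 4 cell division lists or the DNA repair list, which together made up 162 of the 7662 genes tested (Fisher's exact p = 1.01e-22), and 0 of the 25 higher genes did (Fisher's exact p = 1). Kif11, the kinesin that separates spindle poles, fell from 35 ± 8.4 to 17.3 ± 3.51 CPM in shallow libraries (SD, n = 7 and 6) and from 45.6 ± 0.692 to 24.7 ± 0.59 CPM in deep ones (SD, n = 2 and 3; log2 fold change -0.95, SE 0.14, edgeR adjusted p = 0.00111). Bard1, which acts in homologous recombination, had a log2 fold change of -1.03 (edgeR adjusted p = 0.00623). The kinetochore genes Knl1, Cenpe and Knstrn fell with log2 fold changes of -0.93, -0.75 and -0.60, as did Cdc20, an activator of the anaphase-promoting complex, with -0.62, and Trip13, a spindle checkpoint ATPase, with -0.72. Tyms and Tk1, which make thymidylate for DNA synthesis, fell with -0.89 and -0.67, and Chaf1b, a subunit of a histone chaperone, with -0.80. Smc4 and Ncapg, subunits of condensin, fell with -0.53 and -0.73. Anln, Kif4, Ckap2l and Fignl1 had log2 fold changes from -0.84 to -0.64, and Apln, the peptide apelin, and Kcnq1ot1, an imprinted antisense RNA, -0.98 and -0.82.

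In this model 7 genes of the G2 and M list, 7 of the kinetochore and spindle list, 5 of the S phase list, 2 of the condensation list and 2 of the DNA repair list fell over all genes tested, and 27, 32, 24, 8 and 4 did adjusted over the list alone. DESeq2 called 390 genes (165 higher and 225 lower) and limma-voom 100 (49 and 51), and each of these sets held all 52. The count depended on single libraries. It was 11, 14, 24, 25 and 96 without control 1, 2, 3, 4 and 7, and 216, 33, 20, 26, 12, 13, 18 and 18 without scKO 1, 2, 3, 5, 6, 7, 8 and 9. Without the 4 libraries that stood apart it was 617, among them all 52.

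**Figure D4:**
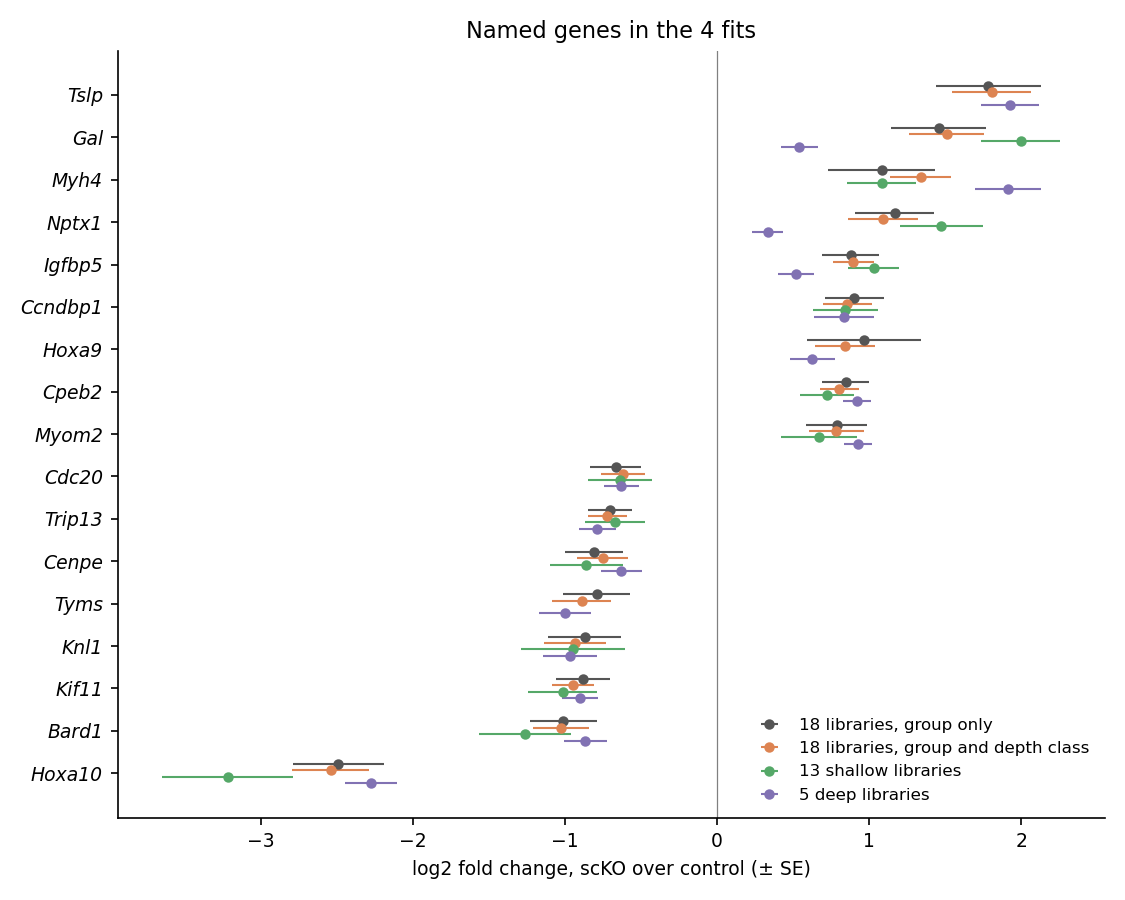
Log2 fold change of scKO over control (points) with its standard error (bars) for 17 genes, in models of all 18 libraries without and with the depth class and of the shallow and the deep libraries alone; genes that were not tested in a model have no point. Hoxa10 lies lowest in each model, at -2.49, -2.54, -3.22 and -2.28.

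Within the 13 shallow libraries edgeR called 3 of 6906 genes, with Gal and Igfbp5 higher (log2 fold change 2.00 and 1.03) and Hoxa10 lower; DESeq2 called 6 and limma-voom 3. The edgeR count was 1 without control 3, 8 or 9 and 5 without scKO 1, and Hoxa10 fell under the count filter there without control 3, 4, 6, 7, 8 or 9. Within the 5 deep libraries it called 1884 of 13136 genes, 960 higher and 924 lower, from 2 controls and 3 scKO libraries. Of the 1230 deep calls tested in shallow libraries, 757 (61.5%) had the same sign there. The kinetochore, S phase and G2 and M lists had medians of -0.26, -0.31 and -0.34 in shallow libraries and of -0.67, -0.68 and -0.68 in deep ones. A test of the difference between the classes called no gene (edgeR interaction term; 473 genes at an unadjusted p under 0.05, lowest adjusted p = 0.388; DESeq2 and limma-voom were not run for it). Without scKO 7 the deep count was 996.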

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

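All tests of explanations in this part, including the counts of other splits of the libraries, were chosen only after the results were seen.

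Cell division genes were lower in scKO on the lists for G2 and M, S phase, and kinetochore and spindle. With an estimated correlation, camera called 7 lists for the real groups. Among 100 splits, the real one included, 1 reached that number, with 1 list in the highest other split. Chance splits of these libraries thus seldom gave as many lists. The 7 also include the condensation, ribosome biogenesis, DNA repair and p53 lists, so this count does not test the 3 lists by themselves. It cannot exclude chance differences between a few animals or cultures, because the labels do not say which libraries share them. The unequal number of deep libraries (2 control and 3 scKO) is argued against, since the highest mean log2 fold change of the 3 lists inside either depth class was -0.31, with camera calls at the preset correlation in both classes (adjusted p from 1.18e-26 to 1.81e-07), though not with an estimated correlation (adjusted p from 0.0513 to 0.245). The 4 shallow libraries that stood apart are argued against as the whole cause, since without them the highest mean was -0.47. Loss of Hoxa10 and an effect of 4-hydroxytamoxifen or Cre cannot be told apart, because 0 control libraries are labelled as given 4-hydroxytamoxifen, so a slower cell cycle after loss of Hoxa10 may be the cause but remains a hypothesis.

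More genes were called once the depth class entered the model, 52 against 1. Spread between the depth classes could account for this, as the biological coefficient of variation was 0.352 without the covariate and 0.209 with it. UMI saturation in the deep libraries is argued against as the whole cause, since counts corrected for UMI collisions gave 5 calls without the covariate. Whether the deep libraries repeat few cultures stays open, because the labels do not tie libraries to cultures; their coefficient of variation was 0.0991. No biological explanation was tested for this pattern.

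Hoxa9 was higher where its neighbour Hoxa10 was lower. Reads of Hoxa10 counted for Hoxa9 are argued against, since Hoxa9 would then fall, and its log2 fold change was 0.84 (SE 0.19) with the depth class as a covariate. A rise shared by the flanking genes is argued against, since Hoxa9 minus the mean of Hoxa7 and Hoxa11 differed by 1.00 log2 units within depth classes (exact two-sided permutation p = 0.00122). Transcripts of the recombined allele that run on into Hoxa9, which lies downstream on the same strand, may be a cause or Hoxa10 may restrain Hoxa9; counts per gene cannot tell these apart, and the log2 fold change of 0.071 of Hoxa11, which lies upstream, decides neither.

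For the other counts of calls, the splits showed the following. Without the depth class, 4 of 100 splits called at least the 1 gene of the real groups, the real one included. Chance thus seldom gave as many calls, but at this share it is not excluded. The highest other split called 931 genes and had all deep libraries on 1 side, which points to the structure of the samples, and the model with the depth class gave 52 calls. For those 52 genes, 2 of 100 splits were as large, the real one included. The highest other split called 61, more than the real groups, so chance seldom gave as many calls but is not excluded. Chance could not be excluded for the 8 lists camera called at the preset correlation (5 of 100 splits, highest other 8), nor for the 9 lists called with the depth class (7 of 100, highest other 11). It could not be excluded for the 3 genes called in shallow libraries either (5 of 100 splits); the highest other split called 958 genes and had the 4 libraries that stood apart on 1 side, again a structure of the samples, and without these 4 libraries edgeR called 0 genes (606 at an unadjusted p under 0.05; Hoxa10 was under the count filter, and DESeq2 and limma-voom were not run there). The 5 deep libraries allow 10 splits, too few for a share under 0.05; the real groups gave 1884 genes and the highest other split 0.

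Some single libraries lay far from the other libraries of their group, in 7 of 114 groups of values tested, where chance alone gives about 5.7. The library scKO 1 had the highest log2 CPM of its group for Cenpe (6.11, others 4.76 to 5.43), Cdc20 (5.97, others 4.90 to 5.28) and Ncl (8.52, others 7.29 to 7.72), and the lowest for Tslp (1.98, others 3.95 to 5.42). Hoxa11 was lowest in scKO 4 (2.54, others 3.95 to 5.13). In controls, Nptx1 was lowest in control 6 (4.28, others 5.71 to 6.15) and Knstrn in control 5 (5.59, others 5.89 to 6.18).

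The effect of scKO differed between deep and shallow libraries for 6 of 33 lists by limma camera on the interaction term at the preset correlation, and for 0 with an estimated correlation (adjusted p from 0.318 to 0.363 for these 6). The mean log2 fold change in deep minus shallow libraries was 0.35 for differentiation and fusion, -0.31 for kinetochore and spindle, -0.27 for S phase, -0.23 for G2 and M, -0.31 for senescence-associated secretory genes and -0.28 for cholesterol synthesis.

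Among features without a gene symbol, ENSMUSGH3 had a count of 121 in scKO 9, or 17.7 CPM, against at most 25 counts in any other library and at most 8.42 CPM in a control library.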

How the results depend on the processing

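The models with the depth class, of shallow or deep libraries alone, with collision-corrected counts, without genes over a count of 2048 and without the 4 libraries that stood apart were chosen after seeing the data; the others were planned. Hoxa10 stayed lower and past the threshold in 34 of 34 alternatives to the model of the group alone that tested it (log2 fold change -3.22 to -2.15, highest edgeR, DESeq2 or limma-voom adjusted p = 0.00635); thinned counts left it untested. Within the shallow libraries alone, its highest edgeR adjusted p when each library was left out was 0.00697, without scKO 3, and without control 3, 4, 6, 7, 8 or 9 it was not tested. The lists for kinetochore and spindle, S phase, G2 and M, condensation, and ribosome biogenesis kept their sign and their camera call at the preset correlation in 35 of 35 settings. With an estimated correlation, camera called 0 lists in the shallow libraries alone and 0 in the deep ones alone. Over 1803 gene values under alternatives, 1554 stayed on the same side of the threshold, 233 newly passed it and 16 in 4 genes reversed. Depth limited the shallow libraries, where 6906 genes passed the count filter against 13136 in the deep ones, and Hoxa9 and Tslp were not tested there.

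The cause of each change below was not tested, except that thinning and subsets use fewer counts or libraries. The count of genes in the model of the group alone, 1 (0 higher, 1 lower), became 32 (19 and 13) with DESeq2, 2 (1 and 1) with limma-voom, 91 (46 and 45) with 1 surrogate variable and 0 (0 and 0) with thinned counts (limma-voom and DESeq2 were not run on these; 361 genes at an unadjusted p under 0.05). It became 52 (25 and 27) with the depth class, 3 (2 and 1) in shallow and 1884 (960 and 924) in deep libraries, 5 (3 and 2) with collision-corrected counts and 54 (26 and 28) with these and the depth class. Without the 4 libraries that stood apart it was 3 (2 and 1), and 617 (271 and 346) with the depth class as well. Leaving out each library gave 1 to 7 genes, 0 to 3 higher and 1 to 4 lower.

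With the depth class, the count of 52 became 359 (164 and 195) with no count filter, 22 (11 and 11) with a stricter filter, 390 (165 and 225) with DESeq2, 100 (49 and 51) with limma-voom, 6 (6 and 0) with thinned counts and 617 (271 and 346) without the 4 libraries. Leaving out each library gave 11 to 216 genes, 6 to 95 higher and 5 to 121 lower. The counts do not settle whether equal numbers pair the libraries. With group means removed, 4 of 9 same-numbered pairs had deviations correlated above 0.1 (range -0.61 to 0.40). There, pairs in different depth classes were negative and pairs in the same class positive, so these values mostly follow depth. With depth class means removed as well, 5 of 9 pairs lay above 0.1 (range -0.07 to 0.25). With those class means left in, 2 controls matched their own number best. With the replicate number as a block, edgeR called 1 gene, and 14 (8 and 6) with the depth class, 9 of them among the 52; under the block Myod1 was -0.032 and Myog -0.013. In deep libraries the count was 1885 with median-of-ratios factors, 1296 with DESeq2 and 996 to 1810 when each library was left out, where a lone control is assumed to vary like the scKO libraries.

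The p53 list lost its call with no count filter (mean 0.13, camera adjusted p = 0.0673), in deep libraries (mean 0.027, median -0.11, direction down, adjusted p = 0.77) and without the 4 libraries with the depth class (mean 0.089, adjusted p = 0.0506); leaving out each library gave means of 0.064 to 0.16. Cholesterol synthesis lost it with no count filter (mean -0.092, adjusted p = 0.172) and in shallow libraries (-0.14, adjusted p = 0.304), with -0.23 to -0.18 when each library was left out. DNA repair lost it with thinned counts (-0.027, median 0.033, adjusted p = 0.84) and in shallow libraries (-0.16, adjusted p = 0.161), with -0.25 to -0.18 when each library was left out. The 1st principal component held 48.6% of variance over all tested genes. The genes with a reversed sign were Mdm2 (-0.012), Pax7 (-0.28), Myod1 (-0.15) and Myog (-0.0031) in deep libraries, where counts of Myod1 and Myog lay near the ceiling of 4096 and cannot show whether either changed; leaving out each library gave -0.052 to 0.15 for Myod1 and -0.066 to 0.097 for Myog. None of these values passed the threshold.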

Other observations

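The tests of explanations in this part, and the genes named for the deep libraries, were chosen only after the results were seen.

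In the 5 deep libraries, camera with an estimated correlation called 0 of 37 lists (lowest adjusted p = 0.18), against 12 with the preset one, so the counts of called list members below are not shown to exceed those of other genes. On the higher side, Pvalb, the calcium buffer of fast fibres, rose with a log2 fold change of 2.53 (SE 0.19; edgeR adjusted p = 3.17e-05), and Cox8b, a muscle subunit of cytochrome oxidase, with 1.57, Tcap, which caps titin at the Z-disc, with 1.22, Fxyd1, a regulator of the sodium pump, with 1.07 and Mybpc1, a myosin-binding protein, with 1.04. Myom2, Myom1 and Unc45b, a myosin chaperone, rose with 0.93, 0.86 and 0.71. The differentiation and fusion list had 17 of 47 members higher and 0 lower over all genes tested (median 0.25; camera adjusted p = 6.39e-06, but adjusted p = 0.78 with an estimated correlation). Nuclear oxidative phosphorylation genes had 7 of 75 members higher and 0 lower (adjusted p = 0.000559, and adjusted p = 0.78 with an estimated correlation).

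On the lower side in the deep libraries, 58 of 71 kinetochore and spindle genes, 49 of 64 S phase genes and 49 of 57 G2 and M genes fell, as did 16 of 60 DNA repair and damage genes. Ccnf, Ccna2 and Ccnb1, cyclins of the later cell cycle, had log2 fold changes of -1.10, -0.77 and -0.72, Cdca8, a chromosomal passenger protein, -0.83, and Rb1, which restrains entry into S phase, 0.67, each an edgeR call. The DNA damage genes Topbp1 and H2afx fell with -0.76 and -0.81, and Dkc1, which modifies ribosomal RNA, with -0.81. Cyp51 and Sqle, enzymes of cholesterol synthesis, both fell with -1.02, in a list with 13 members lower and 3 higher. Stmn2, a regulator of microtubules, fell with -1.65.

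Levels of the G2 and M list and of the differentiation list ran against each other in the 9 shallow libraries that did not stand apart, a set defined from the data. With group means removed, Pearson's r was -0.89 (exact permutation p = 0.0059 over 2880 pairings within groups) and Spearman's rho -0.87 (exact permutation p = 0.0101). This was the only pair of lists correlated, but the pair and the libraries were picked after the results were seen. The p-values take no account of that choice. Over all 13 shallow libraries, of which 4 lie apart from the other 9, r was weaker at -0.59, with no test run. Without the 2 libraries farthest from the median on the G2 and M list, r was -0.74 over 7 of the 9. Cultures further into differentiation may hold fewer cycling cells, a hypothesis this correlation does not exclude; the 4 shallow libraries that stood apart and the 5 deep ones are too few for a test of their own.

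Sox10 and Ngfr, markers of Schwann and neural crest cells, had opposite signs in the depth classes, while Pmp22 and Ncam1 of the same list were negative in both. Sox10, the transcription factor of that lineage, was 6.73 ± 2.29 CPM in deep controls and 25.7 ± 7.35 CPM in deep scKO (SD, n = 2 and 3; log2 fold change 1.96, edgeR adjusted p = 0.00389), and 88.2 ± 55.7 and 33.5 ± 23.5 CPM in shallow ones (SD, n = 7 and 6; -1.35, edgeR adjusted p = 0.80). In the deep libraries Cdh19 and Ngfr rose with 2.47 and 1.10 (edgeR adjusted p = 0.00454 and 0.0137; Ngfr 0.0597 without control 2), and in the shallow ones Ngfr had -1.22 (edgeR adjusted p = 0.729). Pmp22 had -0.71 in shallow and -0.18 in deep libraries, and Ncam1 -0.05 and -0.09, none an edgeR call. The interaction of group and depth class was 3.27 for Sox10 (SE 0.90; edgeR adjusted p = 0.441), so the difference between the classes was not called. A varying share of Schwann cells could give such values, but Mbp, an abundant myelin gene, had -0.37 (SE 0.21) in the deep libraries, within 2 standard errors of 0, which leaves it undecided. Of the 10 genes of this list 4 passed the count filter over all libraries and in the shallow ones and 8 in the deep ones, and the labels name no cell sort. The most abundant, Ncam1, is also expressed by muscle cells and took 69.6% of the list's summed CPM.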
